A study of Homo sapiens with 36 samples.

How the data were processed

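The series measured RNA by sequencing in 36 libraries of H1 human embryonic stem cells and 2 RUNX1 knockout lines made from them, during differentiation to blood on days 6, 9, 12 and 16. Per the labels' protocols, cells were aggregated and then grown flat in medium with BMP4 and VEGF, then with VEGF and for a time an inhibitor of TGF-beta receptors, without added blood cytokines. Library preparation followed standard Illumina protocols from total RNA, per the labels. The submitters' processing notes name bcl2fastq, STAR 2.7, RSEM and Bowtie2 and the builds hg38 and mm10, with no role or order, and the normalization tool is not given in the sources used here.

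The authors deposited 1 table of 18762 genes by 36 libraries, with the gene's coordinates, a GC column in percent as deposited, and whole-number values treated here as a score of unknown scale. These deposited values are not counts. All 36 columns hold the same sorted values with the same total, the highest value of 154610 occurs 10 times in each, once in each of 10 GC classes of equal size, and the medians of the GC classes lie between 284 and 286. Such values arise when genes are ranked within GC classes and libraries are then given a common distribution, and no header or label records that step. Read depth per library and the counting error of low genes are therefore unknown, and no interval that needs counts is given. Each column holds 665 zeros, or 3.54% of genes. A gene at the top of its GC class cannot rise further, and H19, EEF1A1, COL3A1 and COL1A2 hold 1 value each in all 36 libraries.

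The design written beforehand assumed counts. The score was instead tested on a log scale, after division of every column by 19.841, to give ppm, which is the same factor for all. Of the gene IDs, 18684 were found in GENCODE release 29 (hg38), 17680 with identical coordinates. 25 gene names turned into dates were repaired from their IDs, and 20 entries share a name with another. Genes at 1 ppm or more in at least 3 libraries were tested, which kept 17400 and left out 1362.

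Changes were tested in R 4.3.3 with limma 3.58.1 on log2(ppm + 1) with an intensity trend. All 36 libraries entered 1 fit with 12 group means, 24 residual degrees of freedom and a median prior of 4.69, because all groups then share 1 estimate of the spread. Contrasts were both knockout lines (mean of their group means) minus WT on each day, each line minus WT, line 38 minus line C4 on each day, WT on each later day minus day 6, the knockout lines at day 16 minus day 6, and the difference of that change between genotypes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and p-values are two-sided. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over lists and days.

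Before the data were examined, 27 gene lists with 402 members were fixed, of which 365 members are in the table, together with the design, the alternatives and the rule for naming genes. The lists were pluripotency, early mesoderm, endothelial, arterial endothelial, haematopoietic transcription factors, pan-haematopoietic, erythroid, megakaryocyte, myeloid, mast cell and granulocyte, lymphoid, mesenchymal stem cell surface, fibroblast matrix, epithelial-mesenchymal transition regulators, smooth muscle and pericyte, cardiac, bone with cartilage and fat, endoderm and epithelium, neuroectoderm, TGF-beta and BMP targets, RUNX and core binding factor family, HOXA cluster, cell cycle, interferon response, hypoxia and glycolysis, immediate-early and heat shock, and mitochondrial transcripts. No mitochondrial transcript matched the table, so that list was not analysed here. CCN1 and CCN2 were matched under their older names CYR61 and CTGF. CD44, MMRN1, RUNX2 and SOX17 are in 2 lists each. A result for a list member that is withheld for evaluation is not reported here.

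Named genes are RUNX1, members of the lists, and for each day the 6 highest and 6 lowest genes that were called in the mean contrast and in both lines with the same sign, had all 6 knockout libraries outside the range of the 3 WT libraries, and averaged at least 5 ppm in the higher genotype. For the time comparisons 5 and 5 and for line 38 against line C4 3 and 3 per day were taken with the same minimum. Clone names, XIST and Y-linked genes were passed over. This gave 394 genes.

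The fit was tested on simulated data in which every line had the WT mean of the day, with 100 of 17400 genes changed at each of 2 sizes. Noise had the fitted spread of each gene and was independent between libraries, so shared handling was not tested. The changed genes were drawn above a minimum level, so recovery of low genes was not tested either. For the knockout comparison at day 6 it recovered 100 of 100 genes at a log2 fold change of 1.5 and 100 of 100 at 3, with 1 of 17200 unchanged genes called. At day 12 it recovered 99 and 100 with 1 unchanged gene called, for line 38 against line C4 at day 6 98 and 99 with 1, and for the genotype by time term 93 and 100 with 4. For the shared WT libraries, 20 data sets of unchanged groups were simulated.

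Alternatives were pseudocounts of 0.1 and 5, no filter and a stricter filter on low values, median-ratio and quantile scaling, a fit to the compared groups alone, no minimum fold change, a fit to each day alone, a replicate block, an estimated correlation for lists, and each library left out in turn. Leaving out the third library of each line at day 12, list tests of each line against WT, the erythroid test of line 38 at day 12 with each library left out, and list tests with the block were added after the data were seen. The count-based tools planned as an alternative were not run, because the values are not counts. Other splits of the samples were drawn up to 100 per comparison. All 36 libraries were used and 0 were left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.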

Results

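RNA from H1 human embryonic stem cells differentiating towards blood had been sequenced in 36 libraries. The libraries came from the parental line, called WT here, and from 2 RUNX1 knockout lines named 38 and C4 in the labels, at days 6, 9, 12 and 16, with 3 libraries per line and day. RUNX1 is a transcription factor needed for blood cells to emerge from haemogenic endothelium, and the design describes a tdTomato and venus reporter targeted by TALENs to the untranslated part of its exon 3. The series' title sets haematopoiesis against the development of mesenchymal stem cells after RUNX1 is lost. The labels do not say whether RNA came from whole cultures or from sorted cells, nor whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples. Read depth is unknown, because every library had been brought to the same set of values with the same total. Levels are given as parts of that total (ppm, with 19.841 deposited units to 1 ppm). Group values are means ± SD over n = 3 libraries, and fold changes are on the log2(ppm + 1) scale, which understates changes of low genes. Adjusted p-values of genes come from limma with Benjamini-Hochberg adjustment, and those of gene lists from camera with the same adjustment.

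RUNX1 itself (chromosome 21, 34787801 to 36004667 in hg38) was low in all 24 knockout libraries, whose highest level was 6.05 ppm, against 31.4 in the lowest WT library. In WT it stood at 35.6 ± 5.05 (SD, n = 3) at day 6, 48.9 ± 3.53 (SD, n = 3) at day 9, 115 ± 23.3 (SD, n = 3) at day 12 and 64.8 ± 3.07 (SD, n = 3) at day 16. Line 38 held 3.65 ± 2.09, 1.63 ± 0.191, 0.571 ± 0.249 and 0.538 ± 0.210 on those days, and line C4 held 1.38 ± 0.304, 1.44 ± 0.204, 1.19 ± 0.233 and 1.23 ± 0.949. The log2 fold change of the mean of both lines against WT was -3.50, -4.30, -5.96 and -5.20 (SE 0.20 each, limma adjusted p = 4.2e-13, 6.0e-16, 1.8e-20 and 3.6e-19). All 36 libraries thus carried the RUNX1 level that their label names.

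**Figure D1:**
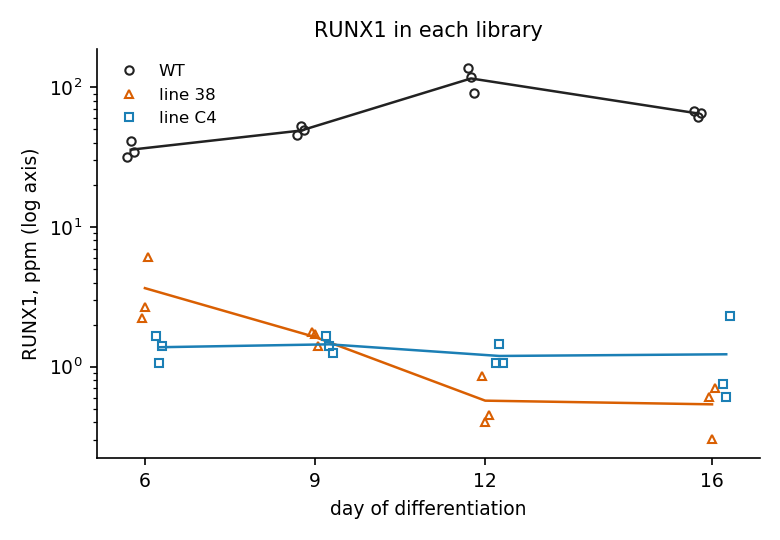
RUNX1 level in ppm (vertical log axis) in each of the 36 libraries by day of differentiation, with points for libraries and lines joining the means of the 3 libraries per group. All 24 knockout libraries lie at or below 6.05 and all 12 WT libraries at or above 31.4.

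The comparison of both knockout lines with WT on each day asked which genes differed between them. Its p-values leave out the spread between knockout lines. With a single parental line, loss of RUNX1 cannot be told apart from other differences between the lines. From day 9 on most of the genes with the largest falls were blood genes, and days 12 and 16 had the most genes past the threshold. Of 17400 genes tested, 213 were higher and 320 lower at day 6, 419 and 673 at day 9, 1684 and 1728 at day 12, and 1575 and 1653 at day 16. These counts depend on how low genes are treated, since the 533 genes of day 6 became 175 with a pseudocount of 5 and 867 with one of 0.1. The median log2 fold change of all genes was 0.01, 0.03, 0.13 and 0.13, and after rescaling by median ratios 0.00, 0.01, 0.01 and 0.01, so the fold changes at days 12 and 16 carry a shift of about that size. The first principal component, with 39.3% of the variance, separated the WT libraries of days 12 and 16 from every knockout library. At day 12 the third library stood apart from the other 2 in WT and line 38, with a lowest correlation of 0.973 and 0.970, against 0.989 and 0.992 between the other 2. In line C4 the third library correlated at 0.978 with library 2 but at 0.987 with library 1, near the 0.989 between those 2.

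Each line was also set against WT alone, to ask whether both knockout lines differed from it in the same genes. Line 38 had 223, 869, 3270 and 3067 genes past the threshold on the 4 days and line C4 had 1345, 1724, 3791 and 3627. Of these, 30, 161, 1243 and 1143 were higher in both lines and 111, 458, 1520 and 1394 lower in both, while 4, 5, 5 and 2 went opposite ways. With a pseudocount of 5 the 141 shared genes of day 6 became 47. Independent lists of those sizes would share 1.92, 12.7, 176 and 158 higher genes and 6.98, 31.6, 180 and 162 lower ones. In 20 data sets of unchanged groups, both lines shared 0 genes when set against the same simulated WT libraries. All libraries, WT included, were drawn independently around the WT mean of the day. The deviations of the real WT libraries were therefore not tested. The covariance of the fold changes of both lines was 0.0881, 0.278, 1.06 and 1.09, against 0.0228, 0.0232, 0.0227 and 0.0230 in the simulation, a difference of 0.0652, 0.255, 1.04 and 1.06. The correlation of those fold changes across genes, which are not independent replicates, was 0.445, 0.769, 0.943 and 0.937, against 0.501, 0.505, 0.498 and 0.502 simulated. The 3 WT libraries per day could not be split, so part of the overlap beyond that of independent lists may come from the shared controls.

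At day 6 both knockout lines had lower HOXA cluster genes, and endothelial genes were lower mainly in line C4. All 5 HOXA cluster genes tested, which set position along the body axis, were lower in the knockout, with a median log2 fold change of -1.85 (camera adjusted p = 1.63e-11, and adjusted p = 0.00011 with an estimated correlation). HOXA9 stood at 16.3 ± 3.30 (SD, n = 3) in WT, 4.67 ± 0.295 in line 38 and 3.09 ± 1.18 in line C4, and HOXA11 at 11.5 ± 1.45, 1.73 ± 0.457 and 2.72 ± 1.05. Of 22 endothelial genes 8 were lower and none higher, with a median of -0.88 (camera adjusted p = 3.11e-16, and adjusted p = 0.04 with an estimated correlation). Line C4 carried most of this, with 16 of 22 lower than in WT and a median of -1.39 (camera adjusted p = 2.35e-16, and adjusted p = 0.0411 with an estimated correlation). Line 38 had 1 lower (2 when adjusted over the list alone) and a median of -0.25 (camera adjusted p = 0.000139, and adjusted p = 0.401 with an estimated correlation). The tight junction gene CLDN5 stood at 39.8 ± 1.98 in WT, 28.1 ± 5.16 in line 38 and 1.26 ± 1.01 in line C4. The clotting factor gene VWF stood at 46.2 ± 5.25, 21.5 ± 10.5 and 13.8 ± 1.99. Of 13 arterial endothelial genes 5 were lower, among them the chemokine receptor gene CXCR4 and the gap junction gene GJA4 (camera adjusted p = 3.99e-08, and adjusted p = 0.0683 with an estimated correlation). They were lower mainly in line C4 as well, with 8 against 1 in line 38. The count of 5 was 3 without WT library 2, WT library 3, line 38 library 2 or line C4 library 1.

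At day 6 most of the blood lists had more lower genes in line C4 than in line 38. Of 20 pan-haematopoietic genes, most of them active across many kinds of blood cell, 4 were lower (camera adjusted p = 3.39e-09, and adjusted p = 0.00296 with an estimated correlation), with 9 in line C4 and 2 in line 38. The 4 were CD33, VAV1, WAS and CORO1A, a sialic acid receptor and 3 signalling or actin regulators of blood cells. WAS stood at 5.07 ± 1.01 in WT, 1.02 ± 0.562 in line 38 and 0.672 ± 0.105 in line C4. Of 19 haematopoietic transcription factors 2 were lower, SPI1 and MECOM (camera adjusted p = 0.00736, and adjusted p = 0.397 with an estimated correlation). Only 1 was called without WT library 3, line 38 library 1 or line C4 library 1. This fall came from line C4, with 4 lower (5 when adjusted over the list alone) and 1 higher (camera adjusted p = 0.000211, and adjusted p = 0.228 with an estimated correlation), while line 38 had none called (camera adjusted p = 0.835). Of 14 megakaryocyte genes 3 were lower, the platelet integrin genes ITGA2B and ITGB3 and the platelet granule gene MMRN1 (camera adjusted p = 0.000716, and adjusted p = 0.397 with an estimated correlation). In line C4 6 were lower and in line 38 1 (camera adjusted p = 0.000171 and 0.277, and adjusted p = 0.317 and 0.771 with an estimated correlation). The myeloid list had 5 of 20 lower (camera adjusted p = 0.0902), among them CSF1R, the receptor for a macrophage growth factor. The mast cell and granulocyte list had 2 of 8 lower (camera adjusted p = 0.0630). Of these, HDC makes histamine and stood at 10.2 ± 2.10 in WT, 1.66 ± 0.811 in line 38 and 0.454 ± 0.400 in line C4. Of 19 erythroid genes 4 were lower, all globin genes, and 7 lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.000794, and adjusted p = 0.52 with an estimated correlation). Line C4 had 12 lower and line 38 none lower and 1 higher (camera adjusted p = 1e-07 and 0.0877, and adjusted p = 0.252 and 0.742 with an estimated correlation). The embryonic globin gene HBE1 stood at 642 ± 316 in WT, 720 ± 202 in line 38 and 7.86 ± 4.99 in line C4. Counts adjusted over the list alone were equal to those adjusted over all genes unless given otherwise.

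The genes that led the day 6 comparison lay in all 6 knockout libraries outside the range of the 3 WT libraries and passed the threshold in each line. The lowest was CTHRC1, a secreted protein of the collagen matrix, at -4.61 (SE 0.19, adjusted p = 1.27e-16). STMN2, a microtubule regulator of neurons, followed at -3.76, MAGEH1, a MAGE family gene, at -3.73, RUNX1 at -3.50, the collagen gene COL21A1 at -3.20 and IQCA1 at -2.97. The highest were S100A14, an epithelial calcium-binding protein, at 3.56 (SE 0.44, adjusted p = 1.66e-06), and the Nodal co-receptor gene CFC1 at 2.73. Then came the apolipoprotein genes APOA2, APOA1 and APOA4, made in liver and gut, the last 2 at 2.59 and 2.24, and the tight junction gene CLDN3 at 2.50. With a pseudocount of 5 APOA4 was no longer past the threshold, at 1.25 with a limma adjusted p of 0.052.

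At day 9 the blood programme of WT had begun, and white cell and platelet genes were lower in both knockout lines. All 14 megakaryocyte genes were lower, with a median of -2.83 (camera adjusted p = 3.15e-17, and adjusted p = 0.0156 with an estimated correlation). The platelet chemokine gene PF4 stood at 77.1 ± 34.0 in WT, 1.13 ± 0.954 in line 38 and 0.974 ± 0.580 in line C4. PLEK, a signalling protein of platelets and white cells, stood at 111 ± 31.9, 0.269 ± 0.254 and 0.269 ± 0.0582. Of 19 haematopoietic transcription factors 17 were lower, with a median of -1.93 (camera adjusted p = 2.09e-18, and adjusted p = 0.00283 with an estimated correlation). Among them SPI1, which directs myeloid development, changed by -3.35 (SE 0.23, adjusted p = 4.02e-12), MYB, a factor of blood progenitors, by -3.27 and GATA1, which directs red cells and megakaryocytes, by -3.23. Of 20 pan-haematopoietic genes 18 were lower (camera adjusted p = 6.02e-23, and adjusted p = 2.13e-05 with an estimated correlation), the exceptions being CD34 at -0.84 and CD44 at 0.19, surface proteins that other cells carry too. Of 20 myeloid genes 10 were lower (camera adjusted p = 6.09e-08, and adjusted p = 0.0299 with an estimated correlation). MPO, the peroxidase of neutrophil granules, stood at 109 ± 31.9 in WT, 0.370 ± 0.278 in line 38 and 0.470 ± 0.191 in line C4. The mast cell and granulocyte list had 4 of 8 lower (camera adjusted p = 3.86e-05, and adjusted p = 0.0893 with an estimated correlation). The erythroid list had 10 of 19 lower (camera adjusted p = 0.000267, and adjusted p = 0.477 with an estimated correlation). In line C4 14 were lower (15 when adjusted over the list alone), and in line 38 4 lower and 1 higher (camera adjusted p = 2.25e-08 and 0.52, and adjusted p = 0.229 and 0.851 with an estimated correlation).

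Outside blood, interferon response genes and endothelial genes were lower at day 9. Of 12 interferon response genes 8 were lower (camera adjusted p = 1.79e-10, and adjusted p = 0.04 with an estimated correlation). The antiviral gene MX1 stood at 32.4 ± 9.63 in WT, 0.386 ± 0.105 in line 38 and 0.840 ± 0.105 in line C4. Of 22 endothelial genes 11 were lower (camera adjusted p = 1.12e-09, and adjusted p = 0.132 with an estimated correlation), while the VEGF receptor gene KDR stood at 0.22 and did not pass. In line C4 17 were lower and in line 38 4 (camera adjusted p = 5.9e-12 and 5.78e-05, and adjusted p = 0.0979 and 0.373 with an estimated correlation). The arterial list had 3 of 13 lower (camera adjusted p = 0.00188, and adjusted p = 0.341 with an estimated correlation). In line C4 9 were lower and in line 38 none (camera adjusted p = 1.59e-05 and 0.335, and adjusted p = 0.166 and 0.769 with an estimated correlation). The count of 3 was 0 without WT library 1, 1 without WT library 2 or line 38 library 3, and 5 without line 38 library 2. Of the HOXA genes 4 of 5 were lower (camera adjusted p = 8.3e-05, and adjusted p = 0.0135 with an estimated correlation). The cell cycle list had 2 of 17 lower, PCNA and CCNE2, and 1 without WT library 2 or line 38 library 3 (camera adjusted p = 7.85e-05, and adjusted p = 0.398 with an estimated correlation). The genes that led the day were PLEK, MPO, PF4, CTHRC1, the eosinophil granule gene PRG2 and the neutrophil oxidase gene NCF4 on the lower side, from -6.44 (SE 0.25, adjusted p = 8.88e-18) to -4.81 (SE 0.19, adjusted p = 8.88e-18). On the higher side they were AHNAK, PRTG, CLSTN2, the peptide transporter gene SLC15A1, the lipoxygenase gene ALOX15 and SH3GL2, from 2.68 (SE 0.32, adjusted p = 1.71e-07) to 2.21 (SE 0.28, adjusted p = 5.54e-07). AHNAK, a large scaffold protein, reached the highest value a library can hold in the knockout lines, which limits its fold change.

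At days 12 and 16 all megakaryocyte and at least 19 of 20 myeloid genes were lower in each knockout line, whereas red cell genes of line 38 at day 12 varied between its libraries. MPO rose in WT to 3387 ± 853 (SD, n = 3) at day 12 and stood at 0.302 ± 0.101 in line 38 and 0.571 ± 0.378 in line C4, a log2 fold change of -11.19 (SE 0.30, adjusted p = 1.05e-22). PPBP, a platelet chemokine gene, stood at 2312 ± 1397 in WT at day 16, 0.302 ± 0.0504 in line 38 and 0.151 ± 0.151 in line C4, a change of -10.71 (SE 0.31, adjusted p = 2.82e-22). All 20 myeloid genes and all 14 megakaryocyte genes were lower on both days. The myeloid median was -5.07 at day 12 and -6.38 at day 16 (camera adjusted p = 1.72e-21 and 1.91e-24, and adjusted p = 0.000274 and 0.000116 with an estimated correlation). The megakaryocyte median was -5.65 and -5.49 (camera adjusted p = 3.83e-16 and 1.43e-16, and adjusted p = 0.0175 and 0.0174 with an estimated correlation). At day 16 the macrophage complement gene C1QA stood at 167 ± 53.5 in WT and at 0.0504 ± 0.0873 and 0.118 ± 0.105 in the knockout lines. The neutrophil gene S100A8 stood at 513 ± 253, 0 and 0.118 ± 0.204.

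Of 19 haematopoietic transcription factors 18 were lower on both days (camera adjusted p = 1.34e-15 and 3.15e-17, and adjusted p = 0.00493 and 0.00331 with an estimated correlation). SPI1 stood at 144 ± 10.2 in WT at day 16, 0.386 ± 0.154 in line 38 and 0.722 ± 0.539 in line C4, and the factor gene that was not lower, MECOM, changed by -0.43 and -0.64. Of 20 pan-haematopoietic genes 18 were lower on both days (camera adjusted p = 1.03e-19 and 5.94e-20, and adjusted p = 2.86e-05 on both days with an estimated correlation). PTPRC, the CD45 surface protein of white blood cells, changed by -6.74 (SE 0.14, adjusted p = 1.75e-25) and -6.92 (SE 0.14, adjusted p = 8.34e-26). The mast cell and granulocyte list had 6 of 8 lower at day 12 and 8 of 8 at day 16 (camera adjusted p = 2.32e-08 and 1.14e-11, and adjusted p = 0.0175 and 0.00471 with an estimated correlation). The mast cell tryptase genes TPSAB1 and TPSB2, near-identical copies whose reads could be split, were listed at 0 in both knockout lines. The erythroid list had 10 of 19 lower at day 12 and 11 lower and 2 higher at day 16 (camera adjusted p = 0.0356 and 0.014, and adjusted p = 0.648 and 0.627 with an estimated correlation). At day 12 line 38 had 6 lower and 4 higher and line C4 12 lower, or 6, 5 and 13 when adjusted over the list alone (camera adjusted p = 0.447 and 0.000895, and adjusted p = 0.836 and 0.478 with an estimated correlation). The sum of 9 globin genes was then 6467 ± 4209 in WT, 4001 ± 5362 in line 38 and 264 ± 102 in line C4 (SD, n = 3). The third library of line 38 carried its mean, with 10190 against 906 on average in the other 2. Without it line 38 had 8 erythroid genes lower and 1 higher (camera adjusted p = 0.0757, and adjusted p = 0.688 with an estimated correlation). RHAG, a red cell membrane protein, changed by -5.49 (SE 0.36, adjusted p = 8.84e-14) at day 16. SLC4A1, the red cell anion exchanger, changed by 2.01 (SE 0.52, adjusted p = 0.00140) and TFRC, the transferrin receptor, by 1.03 (SE 0.12, adjusted p = 4.01e-08). The lymphoid list had no consistent direction, with 3 of 10 lower and 2 higher at day 12 and 3 lower and 1 higher at day 16 (camera adjusted p = 0.166 and 0.400). Its lower members were IL7R, PTCRA and CD2, receptors of lymphocytes, and the higher one on both days was TCF7, a factor of T cells and of Wnt signalling.

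**Figure D2:**
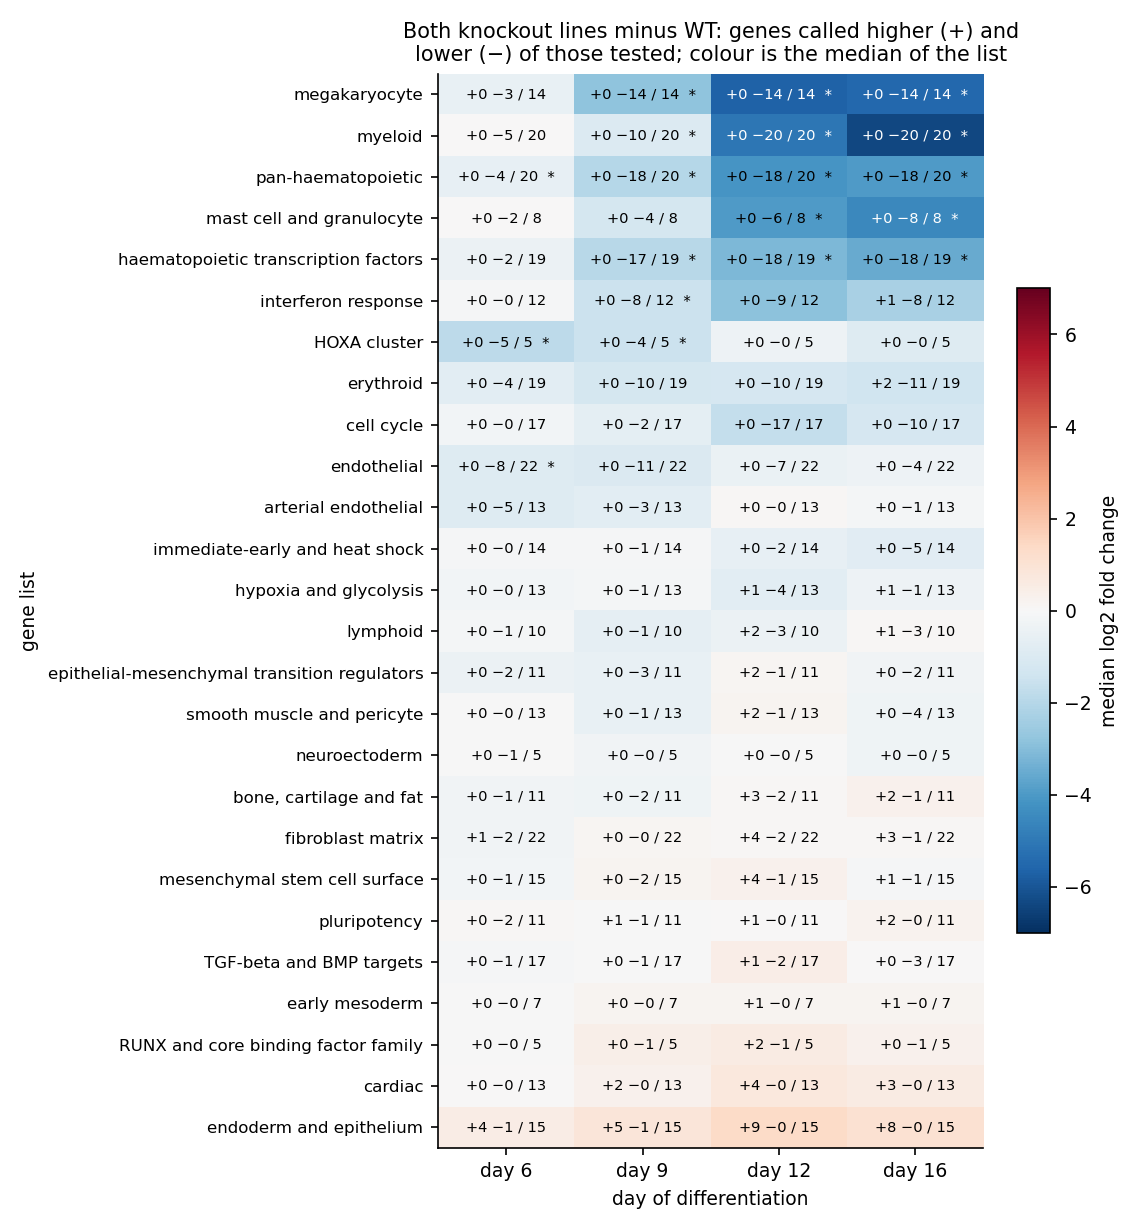
Median log2 fold change of both knockout lines against WT (colour) for each gene list (vertical) on each day (horizontal), with the number of genes called higher and lower of those tested written in each cell and an asterisk where the camera adjusted p with an estimated correlation was under 0.05. The myeloid and megakaryocyte lists reach -6.38 and -5.65, and the endoderm list is the highest on average.

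Cell cycle and interferon genes fell along with the blood genes. All 17 cell cycle genes were lower at day 12 and 10 at day 16, with medians of -1.65 and -1.15 (camera adjusted p = 6.91e-11 and 1.2e-07, and adjusted p = 0.128 and 0.236 with an estimated correlation). The proliferation marker MKI67 stood at 135 ± 61.4 in WT at day 12, 28.8 ± 3.04 in line 38 and 20.1 ± 6.92 in line C4. Of 12 interferon response genes 9 were lower at day 12, and 8 lower and 1 higher at day 16 (camera adjusted p = 2.5e-06 and 3.86e-05, and adjusted p = 0.132 and 0.215 with an estimated correlation). IFI6, an interferon-induced protein, changed by -4.15 (SE 0.23, adjusted p = 1.55e-15) at day 12, while IFIT1, another interferon-induced gene, was higher at day 16, at 1.07 (SE 0.23, adjusted p = 2.6e-04). Of 22 endothelial genes 7 were lower at day 12 and 4 at day 16 (camera adjusted p = 0.0159 and 0.0519, and adjusted p = 0.606 and 0.648 with an estimated correlation). MMRN1, which platelets also hold, was the endothelial member with the largest fall, at -3.83 (SE 0.38, adjusted p = 7.69e-10) and -2.95 (SE 0.38, adjusted p = 1.22e-07). Of the immediate-early and heat shock genes, which respond to handling of cells and to RNA quality, 2 of 14 were lower at day 12, or 5 without WT library 2. At day 16, 5 of 14 were lower, namely FOS, FOSB, JUNB, IER2 and DUSP1 (camera adjusted p = 0.0308, and adjusted p = 0.475 with an estimated correlation).

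The genes that led at day 12 were MPO, PPBP, PLEK, SPP1, PF4 and PRG2 on the lower side, from -11.19 to -9.04 (SE 0.30, adjusted p = 9.58e-21). SPP1 encodes osteopontin, made by bone cells and macrophages, and stood at 1617 ± 712 in WT, 0.689 ± 0.410 in line 38 and 1.83 ± 1.11 in line C4. At day 16 the lower side was led by PPBP, PRG2, the granule proteoglycan gene SRGN at -9.41 (SE 0.23, adjusted p = 7.7e-24), the lysozyme gene LYZ at -9.22, MPO and PLEK. On the higher side day 12 was led by PPP1R1A, a phosphatase inhibitor, at 3.70 (SE 0.27, adjusted p = 1.17e-12), the neuropeptide gene NPY at 3.34 and CCBE1, a secreted protein needed for lymphatic vessels, at 3.32. PCK1, an enzyme of glucose synthesis in liver and kidney, followed at 3.19, with the ephrin receptor gene EPHA7 and OTOL1, a collagen-like protein of the inner ear, both at 3.12. Day 16 was led by PCK1 at 3.59 (SE 0.42, adjusted p = 2.01e-08), AHNAK at 3.38, the phosphate transporter gene SLC34A2 at 3.30, NXPE4 at 3.23, the glutathione transferase gene GSTA1 at 3.17 and the fibrinogen gene FGA at 3.16.

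**Figure D3:**
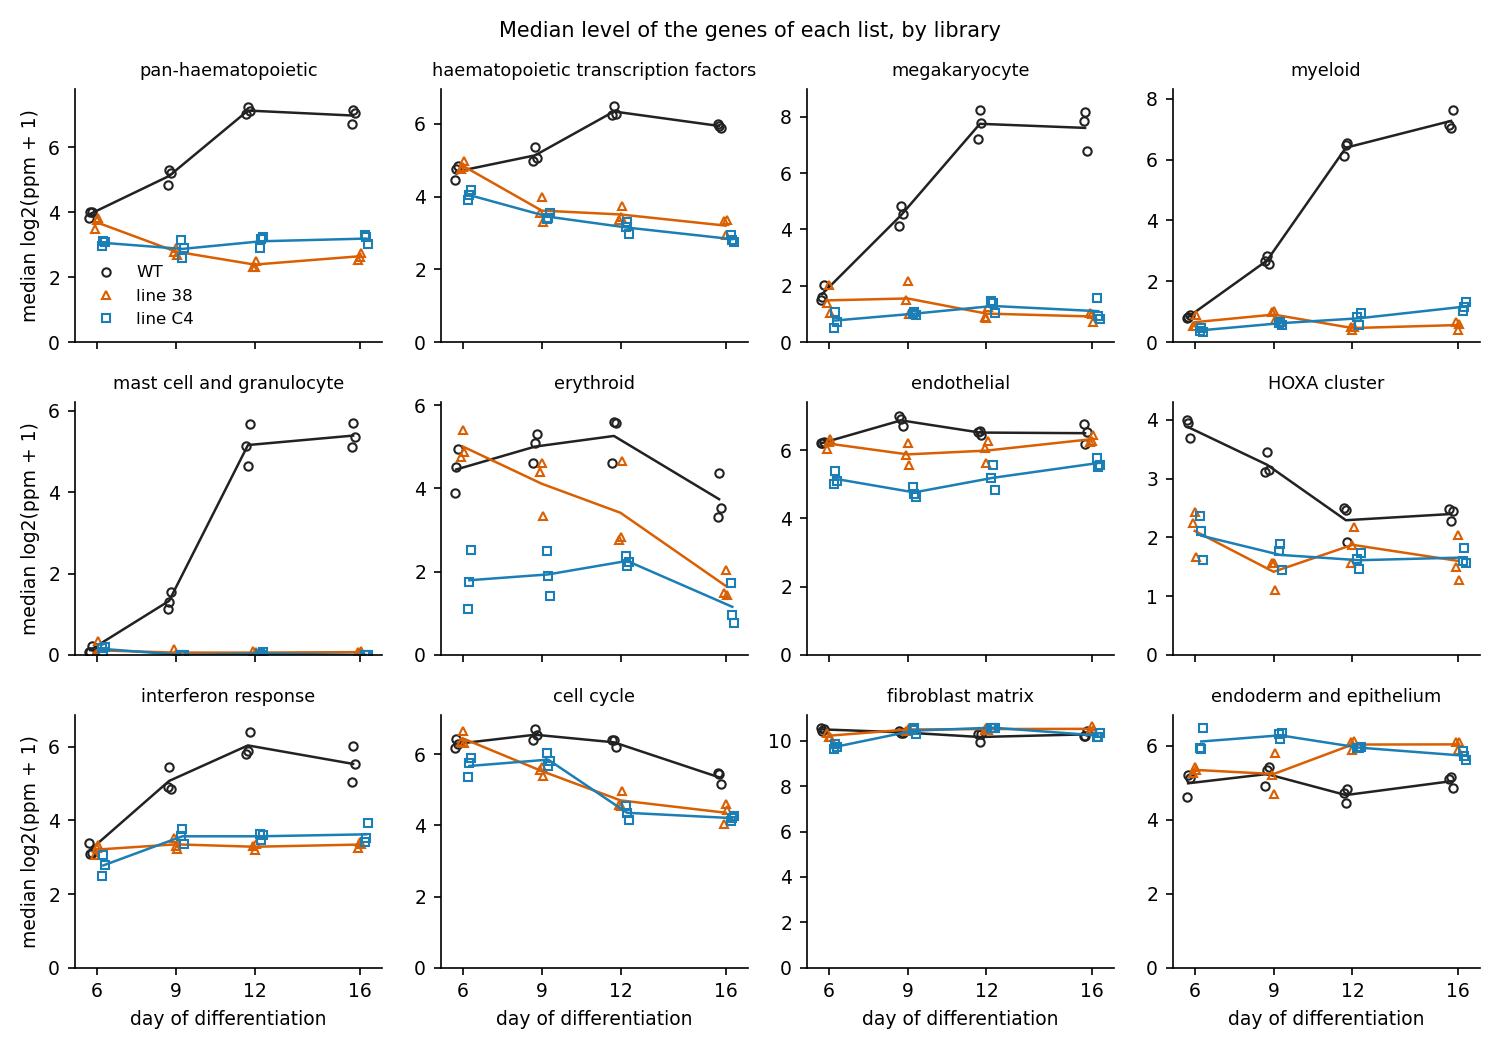
Median log2(ppm + 1) of the genes of 12 lists (vertical axes) in each library by day of differentiation (horizontal axes), with points for the 36 libraries and lines joining the means of 3 libraries per group. The pan-haematopoietic, megakaryocyte, myeloid and mast cell lists lie higher at days 9, 12 and 16 than at day 6 in WT, and at days 12 and 16 below WT in lines 38 and C4.

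The series' title names mesenchymal stem cells, so the lists of mesenchymal genes were set against WT on each day. As lists they did not pass at days 9, 12 or 16, and single members went both ways at days 12 and 16. At day 9 every called member was lower. These were 2 of 15 mesenchymal stem cell surface genes, 3 of 11 epithelial-mesenchymal regulators, 1 of 13 smooth muscle and 2 of 11 bone, cartilage and fat genes. None of 22 fibroblast matrix genes was called then. The day 9 camera adjusted p was 0.899, 0.0664, 0.384, 0.404 and 0.449 in that order. Of 15 mesenchymal stem cell surface genes 1 was lower at day 6 (camera adjusted p = 0.0489, and adjusted p = 0.428 with an estimated correlation). It was NT5E, the CD73 enzyme used to define these cells, at -2.28 (SE 0.20, adjusted p = 4.88e-09). At day 12, 4 were higher and 1 lower (camera adjusted p = 0.400). The higher ones were the adhesion gene ALCAM at 2.10 (SE 0.18, adjusted p = 6.5e-11), the growth factor receptor genes NGFR at 1.15 and PDGFRA at 1.16, and the leptin receptor gene LEPR at 1.46. The lower one was ENG, the CD105 co-receptor, at -1.05. At day 16 ALCAM was higher, at 1.97 (SE 0.18, adjusted p = 2.73e-10), and ENG lower, at -1.13 (SE 0.20, adjusted p = 1.84e-05) (camera adjusted p of the list = 0.912). Without WT library 2 or line 38 library 1 only 1 of them passed. THY1, the CD90 marker, stood at -0.70, -0.60, 0.16 and -0.37 on the 4 days and passed on none.

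Of 22 fibroblast matrix genes 1 was higher and 2 lower at day 6 (camera adjusted p = 0.0083, and adjusted p = 0.128 with an estimated correlation). The lower ones, the matrix protein genes DCN and POSTN, differed between the lines by 4.92 and 2.44 (line 38 minus line C4). DCN stood at 1110 ± 164 in WT, 770 ± 18.6 in line 38 and 29.0 ± 17.2 in line C4. At day 12, 4 were higher, the collagen genes COL5A1 and COL6A2 and the fibulin genes FBLN1 and FBLN5, and 2 lower, TNC and the elastin gene ELN (camera adjusted p = 0.619). At day 16, 3 were higher and 1 lower, with FBLN1 at 1.57 (SE 0.15, adjusted p = 2.61e-10) and the collagen crosslinking gene LOX at -1.11 (SE 0.14, adjusted p = 9.44e-08) (camera adjusted p = 0.964). For part of the list a rise was limited, because 8 of its 22 genes ranked in the top 10 of their GC class in every library and COL3A1 and COL1A2 held the same value in all 36. Of 11 regulators of the epithelial-mesenchymal transition 2 were higher and 1 lower at day 12 and 2 lower at day 16 (camera adjusted p = 0.794 and 0.527). TWIST2 stood at 1.61 and ZEB2, which blood cells also use, at -1.83. The smooth muscle and pericyte list had 2 of 13 higher and 1 lower at day 12 and 4 lower at day 16 (camera adjusted p = 0.912 and 0.166). The day 16 members were the contractile genes ACTA2, TAGLN, MYLK and ACTG2, with ACTA2 at 508 ± 140 in WT, 355 ± 168 in line 38 and 54.4 ± 4.86 in line C4. The bone, cartilage and fat list had 3 of 11 higher and 2 lower at day 12 and 2 higher and 1 lower at day 16 (camera adjusted p = 0.918 and 0.989). SOX9, the regulator of cartilage, changed by 1.80 (SE 0.25, adjusted p = 5e-07) and 1.54 (SE 0.25, adjusted p = 5.95e-06), MSX2, a bone and limb factor, by 1.74 and 1.55, and the lower member at day 16 was SPP1.

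The endoderm and epithelium list was higher in the knockout on all 4 days by the preset-correlation test. Of its 15 genes 4 were higher and 1 lower at day 6, 5 higher and 1 lower at day 9 (6 and 1 when adjusted over the list alone), 9 higher at day 12 and 8 higher at day 16. The camera adjusted p was 3.46e-05, 0.00292, 0.00365 and 0.00161, and adjusted p = 0.12, 0.285, 0.297 and 0.245 with an estimated correlation. APOA1 stood at 103 ± 33.9 (SD, n = 3) in WT at day 16, 365 ± 72.4 in line 38 and 629 ± 94.9 in line C4, a change of 2.25 (SE 0.35, adjusted p = 3.22e-06). TTR, a thyroid hormone carrier made in liver, changed by 2.17, 2.26, 1.85 and 2.17, and HNF4A, the liver and gut transcription factor, by 2.00, 2.10, 1.73 and 2.25. CDH1, the adhesion protein E-cadherin of epithelia, changed by 2.33 (SE 0.15, adjusted p = 8.28e-14) at day 12. The lower member at days 6 and 9 was SOX17, a factor of endoderm that arterial endothelium also expresses. At days 6 and 9, 2 and 1 of the members passed the threshold in each line separately, and at days 12 and 16, 8 and 7. The day 9 call rested on line C4, with 8 higher and 1 lower (camera adjusted p = 0.000161, and adjusted p = 0.157 with an estimated correlation), while line 38 had 1 higher (camera adjusted p = 0.172).

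**Figure D4:**
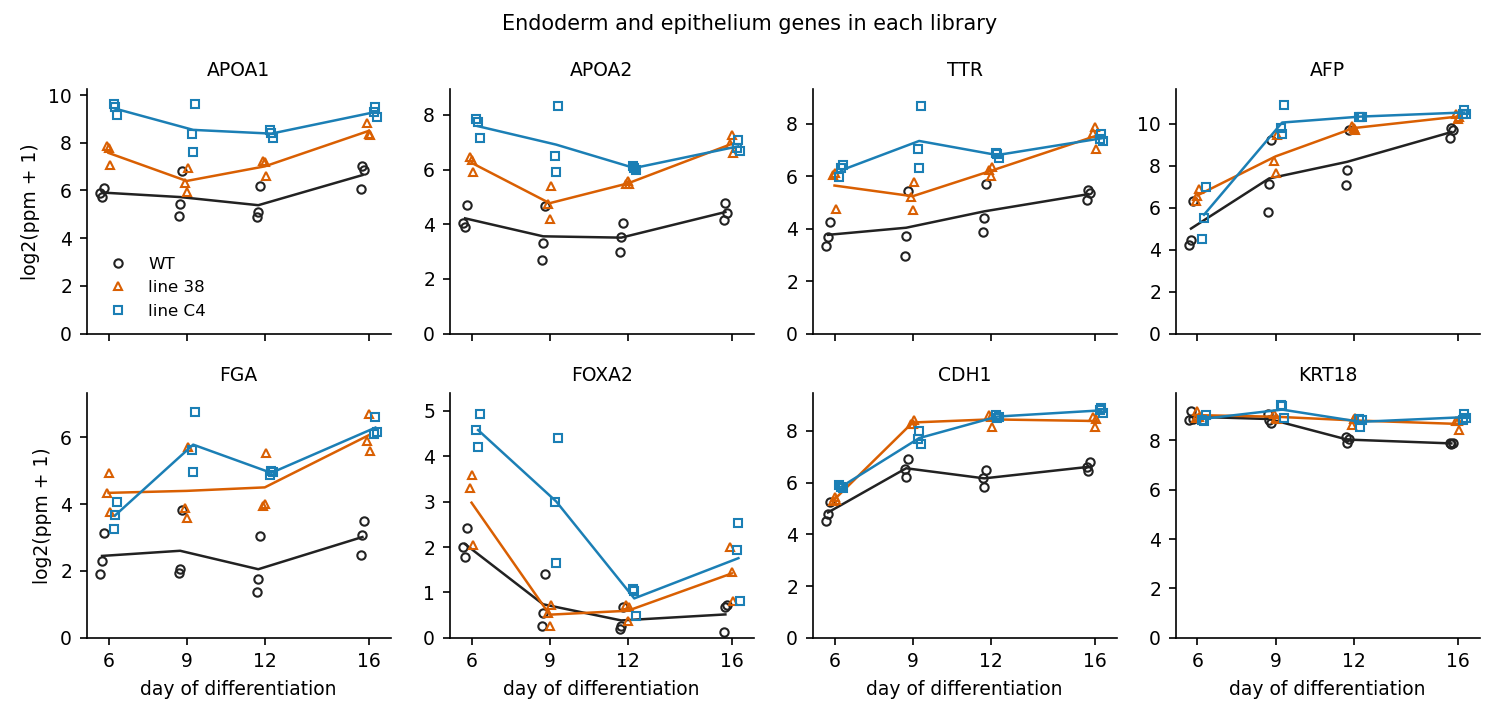
Level of 8 endoderm and epithelium genes, log2(ppm + 1) on the vertical axes, in each library by day of differentiation on the horizontal axes, with points for the 36 libraries and lines joining the means of 3 libraries per group. APOA1 at day 16 averages 103 ppm in WT, 365 in line 38 and 629 in line C4.

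The WT time course asked which genes accompany differentiation in the parental line. White cell and platelet genes rose and pluripotency genes fell. From day 6, 521 genes were higher and 281 lower at day 9, 1684 and 1377 at day 12, and 1998 and 1777 at day 16. Of 14 megakaryocyte genes 12, 14 and 13 were higher at days 9, 12 and 16, of 20 myeloid genes 9, 20 and 19, and of 20 pan-haematopoietic genes 12, 19 and 19. At day 16 the camera adjusted p of these lists was 6.21e-14, 2.28e-23 and 2.02e-16 (adjusted p = 0.0261, 0.000174 and 0.00013 with an estimated correlation). Of 19 haematopoietic transcription factors 3 were higher at day 9 (4 when adjusted over the list alone), 13 at day 12 and 9 at day 16 (day 16 camera adjusted p = 2.43e-05, and adjusted p = 0.111 with an estimated correlation). Of 8 mast cell and granulocyte genes 2, 6 and 8 were higher (day 16 camera adjusted p = 1.27e-09, and adjusted p = 0.00871 with an estimated correlation). Of 12 interferon response genes 10, 11 and 10 were higher (day 16 camera adjusted p = 4.87e-07, and adjusted p = 0.089 with an estimated correlation). The smooth muscle and pericyte list had 5, 6 and 8 of 13 higher and 1 lower on each day (day 16 camera adjusted p = 1.67e-05, and adjusted p = 0.0198 with an estimated correlation). The pluripotency list had 3, 7 and 10 of 11 lower and at day 16 also 1 higher (day 16 camera adjusted p = 3.42e-05, and adjusted p = 0.00613 with an estimated correlation). The stem cell factor gene POU5F1 changed by -4.88 (SE 0.32, adjusted p = 1.23e-13). Of 19 erythroid genes 5 were higher at day 9 (11 when adjusted over the list alone), 9 higher and 1 lower at day 12, and 5 higher and 5 lower at day 16. The camera adjusted p of this list was 2.66e-05, 0.0121 and 0.360 (adjusted p = 0.318, 0.559 and 0.851 with an estimated correlation). Of 14 immediate-early and heat shock genes 7 were higher and 1 lower at day 12. At day 16, 8 were higher (9 when adjusted over the list alone) and 1 lower (camera adjusted p = 0.00893, and adjusted p = 0.307 with an estimated correlation). The genes that led from day 6 to day 16 were PPBP at 10.68 (SE 0.36, adjusted p = 1.97e-20), MPO, the clotting factor gene F13A1, PRG2 and the neutrophil gene S100A9 on the higher side. On the lower side they were POU5F1, SOST, a bone-derived Wnt inhibitor, PCAT14, SLC32A1 and SYTL5. After rescaling by median ratios the lower share of the day 16 calls was 34.5%, against 47.1% as reported.

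In the knockout lines the same interval, day 16 against day 6, held 1571 higher and 1283 lower genes. These are means over both lines, which differed in 1088 genes at day 6, and neither line was tested over time alone. Haematopoietic transcription factors fell in that mean, with 14 of 19 lower and 1 higher (camera adjusted p = 1.27e-06, and adjusted p = 0.0764 with an estimated correlation). At day 6, 10 of the 19 were higher in line 38 than in line C4 and 1 lower. KLF1, a red cell factor, changed by -4.34 (SE 0.29, adjusted p = 1.81e-13). Cell cycle genes fell too, with 15 of 17 lower (camera adjusted p = 1.33e-09, and adjusted p = 0.114 with an estimated correlation). In WT 7 of 17 were lower (camera adjusted p = 0.0108, and adjusted p = 0.553 with an estimated correlation). Smooth muscle genes rose, with 6 of 13 higher and 1 lower (camera adjusted p = 0.000371, and adjusted p = 0.0511 with an estimated correlation). The fibroblast matrix list had 6 of 22 higher and 2 lower (camera adjusted p = 0.0284, and adjusted p = 0.16 with an estimated correlation). The arterial list had 6 of 13 higher and 1 lower (camera adjusted p = 0.00871, and adjusted p = 0.375 with an estimated correlation). Pluripotency genes fell as in WT, with 8 of 11 lower and 1 higher (camera adjusted p = 0.000128, and adjusted p = 0.00868 with an estimated correlation). Early mesoderm genes had 4 of 7 lower (camera adjusted p = 0.00322, and adjusted p = 0.0261 with an estimated correlation). In WT 4 of 7 were lower too (camera adjusted p = 0.00535, and adjusted p = 0.035 with an estimated correlation). The genes that led on the higher side were SERPINE3 at 7.21 (SE 0.21, adjusted p = 1.65e-21), STMN2 at 7.13, the lymphatic and sinusoidal endothelium gene LYVE1 at 6.93, SLC34A2 and the apolipoprotein gene APOC3. On the lower side they were BEX1, SLC32A1, SOST, KLF1 and SCGN, from -4.87 (SE 0.16, adjusted p = 2.36e-20) to -4.18 (SE 0.24, adjusted p = 5.91e-15).

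Whether the knockout effect itself differed between day 16 and day 6 was tested as a genotype by time term, in which 1598 genes were higher and 1639 lower. This term is also a mean over both lines, and genes that led it were not required to pass in each line. The blood lists carried the lower side, with 19 of 20 myeloid, 14 of 14 megakaryocyte, 17 of 19 transcription factor and 8 of 8 mast cell and granulocyte genes lower, and 17 of 20 pan-haematopoietic genes lower and 1, CD44, higher. Their medians were -5.72, -4.52, -3.61, -3.32 and -3.11 (camera adjusted p = 1.65e-27, 7.47e-17, 7.47e-17, 1.34e-12 and 2.14e-18, and adjusted p = 3.62e-05, 0.0121, 0.00228, 0.00228 and 3.62e-05 with an estimated correlation). Interferon and cell cycle lists had medians of -2.42 and -0.90, with 8 of 12 and 8 of 17 lower (camera adjusted p = 8.12e-05 and 1.49e-05, and adjusted p = 0.298 and 0.415 with an estimated correlation). Mesenchymal lists did not pass as lists, with 7 of 22 fibroblast matrix genes higher and 2 lower and 4 of 15 mesenchymal stem cell surface genes higher (camera adjusted p = 0.274 and 0.439). The genes that led were STMN2 at 4.75 (SE 0.49, adjusted p = 3.71e-09), SLC34A2, the neurotrophin receptor gene NTRK3, the monooxygenase gene FMO1 and FREM2, a basement membrane protein, on the higher side. On the lower side they were PPBP at -10.80 (SE 0.44, adjusted p = 4.22e-18), MPO, PRG2, S100A8 and S100A9.

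The comparison of line 38 with line C4 on each day asked how far the 2 knockout lines differed from each other. At day 6 line C4 held far fewer red cell and endothelial transcripts than line 38. The lines differed in 1088 genes at day 6 (547 higher and 541 lower in line 38), 618 at day 9 (281 and 337), 329 at day 12 (196 and 133) and 436 at day 16 (286 and 150). Of 19 erythroid genes 13 were higher in line 38 at day 6 (14 when adjusted over the list alone), 15 at day 9 (16 over the list alone), 11 at day 12 (14 over the list alone) and 2 at day 16. Their median was 1.78 at day 9 (camera adjusted p = 2.92e-15, and adjusted p = 0.122 with an estimated correlation). HBE1 differed by 6.47 (SE 0.94, adjusted p = 9.79e-06) at day 6, HBG2 by 5.51 and HBA1 by 5.29, and these globin genes are uncertain one by one because they overlap or have near-identical copies. Of 22 endothelial genes 14 were higher in line 38 at day 6 and none lower (camera adjusted p = 2.37e-11, and adjusted p = 0.17 with an estimated correlation). Of 19 haematopoietic transcription factors 10 were higher and 1 lower (camera adjusted p = 0.000143, and adjusted p = 0.225 with an estimated correlation). Endoderm genes went the other way, with 4 of 15 lower in line 38 at day 6 (camera adjusted p = 0.00535, and adjusted p = 0.316 with an estimated correlation). At day 9, 5 of 15 were lower and 6 when adjusted over the list alone (camera adjusted p = 0.000182, and adjusted p = 0.18 with an estimated correlation). Among the latter were APOA1 at -2.14 and TTR at -2.11. Smooth muscle genes at day 12 and regulators of the epithelial-mesenchymal transition at day 16 were higher in line 38, with 5 of 13 and 3 of 11 (camera adjusted p = 1.12e-06 and 2.57e-06, and adjusted p = 0.0301 and 0.00167 with an estimated correlation). With the replicate number as a block the smooth muscle list lost its call at the estimated correlation. At day 12 HBE1 and HBZ led the higher side at 3.44 and 2.80, but without line 38 library 3 they stood at 1.97 and 2.15 with limma adjusted p of 0.288 and 0.0664. HBE1 at day 12 was also not past the threshold without line C4 library 1 or 2 (adjusted p = 0.0764 and 0.0986). A fit to day 12 alone gave HBE1 an adjusted p of 0.221 and HBZ 0.0751.

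Of the genes named for this comparison, the one with the largest deficit in line 38 on every day was CBR1, a carbonyl reductase gene. It lies on chromosome 21 at 36069941 to 36073166, past the higher coordinate of RUNX1 (36004667), and SETD4 starts between them at 36034541. CBR1 differed by -4.32 (SE 0.13, adjusted p = 2.66e-20) at day 6 and -4.73 (SE 0.13, adjusted p = 2.04e-21) at day 16. Its mean was 13.0 ppm over the 12 WT libraries, 22.0 over the 12 of line C4 and 0.0294 over the 12 of line 38, where no library exceeded 0.101. Of 13 other expressed genes within 1 Mb of RUNX1, 0 were lower in line 38 on all 4 days by limma. The lower side was also led by MAGEH1, at -3.24 at day 6, KLF8, a transcription factor, at -3.23 at day 9, and CTHRC1, at -3.29 at day 12. The other genes that led were NGFR at -3.24 on the lower side at day 6 and NDUFA4L2, a mitochondrial protein induced by low oxygen, at -3.93 at day 9. On the higher side SLC4A1 stood at 4.01 at day 9, PALMD at 2.82 at day 12 and 3.48 at day 16, the calcium pump gene ATP2B2 at 3.00 and the receptor gene TNFRSF19 at 2.85 at day 16.

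**Figure D5:**
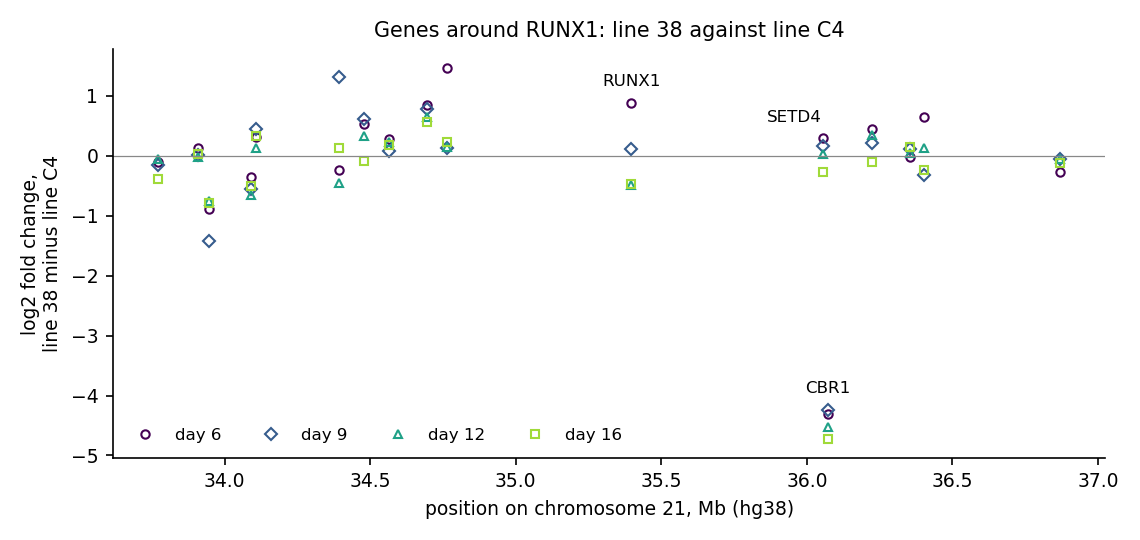
Log2 fold change of line 38 minus line C4 (vertical axis) for the expressed genes around RUNX1 by position on chromosome 21 in Mb of hg38 (horizontal axis), with 1 symbol per gene and day from means of 3 libraries per group. CBR1 lies between -4.73 and -4.24 on the 4 days.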

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

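The tests of explanations for the line differences were chosen after those differences were seen, and the bounds for a delay were widened once its value was known, whereas the splits of the samples were planned before the data were examined.

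The effect of the knockout differed between day 16 and day 6 in 3237 genes by a test of the difference itself, 184 of them among the named genes. List medians of that difference were -3.61 for haematopoietic transcription factors, -3.11 for pan-haematopoietic, -4.52 for megakaryocyte, -5.72 for myeloid, -3.32 for mast cell and granulocyte, -0.91 for cell cycle and -2.42 for interferon response genes. Of 100 splits of the libraries 2 gave as many genes, the real one included, a share under 0.05. The other, with 3821 genes, reshuffled the labels of day 6 and kept those of day 16, so it carried the structure of the late samples. Such splits mix libraries of lines that differ, so they cannot tell an effect of RUNX1 from one of the line.

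The change from WT differed between lines 38 and C4 in 1088 genes at day 6, 618 at day 9, 329 at day 12 and 436 at day 16, by a test of the lines against each other. Of the named genes 106, 75, 43 and 48 did so. The 10 splits of the 6 libraries per day are too few to reach a share under 0.05, and the highest other split gave 1, 3, 204 and 44 genes. On the day of their smallest p, lists that differed between the lines had medians (line 38 minus line C4) of -0.42 for pluripotency at day 9, 1.14 for endothelial at day 6, 0.86 for arterial at day 9, 1.06 for haematopoietic transcription factors at day 6 and 0.35 for pan-haematopoietic genes at day 6. Further medians were 1.78 for erythroid at day 9, 0.89 for megakaryocyte at day 6, -0.74 for endoderm at day 9, 0.45 for TGF-beta and BMP targets at day 16, 0.65 for cell cycle at day 6 and -0.78 for cardiac genes at day 9. The last were 0.58 for regulators of the epithelial-mesenchymal transition at day 16, 0.62 for smooth muscle at day 12 and -0.17 for myeloid genes at day 16. On other days the direction was reversed for cell cycle genes, at -0.42 at day 9 (camera adjusted p = 0.000143). So it was for TGF-beta and BMP targets, at -0.29 at day 6 (camera adjusted p = 0.0251). With an estimated correlation, of these lists only the epithelial-mesenchymal regulators and smooth muscle stayed below 0.05, at adjusted p = 0.00167 and 0.0301. With the replicate number as a block smooth muscle no longer did.

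At day 6 line C4 held fewer transcripts of red cells, endothelium and blood factors than line 38. The split of reads between near-identical globin genes is argued against, because the sum of 9 globin genes was 23.6 ± 18.0 ppm in line C4 and 1223 ± 277 in line 38 (SD, n = 3), and the highest library of line C4 held 0.0418 of the lowest of line 38. For the whole set of genes a delay of line C4 in time cannot be told apart from other differences, because 169 of 213 genes that differed between the lines and changed in WT by day 9 lay in the direction of a delay, or 79.3%, and 44 in the other, and the days begin at 6. For the globin genes alone a delay is argued against, because no later library of line C4 exceeded 381, or 0.369 of the lowest library of line 38 at day 6, and its mean fell from 264 at day 12 to 93.4 at day 16. Line 38, whose RUNX1 transcript was also low, averaged 3081 ± 2239 ppm of globin at day 9 (SD, n = 3), with its lowest library at 699. At day 6 RUNX1 stood at 3.65 ± 2.09 ppm in line 38 and 1.38 ± 0.304 in line C4 (SD, n = 3). Whether this remaining RUNX1 transcript bears on the difference was not tested. A difference between the 2 lines in how they were derived stays open as untested.

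CBR1 was near 0 in all 12 libraries of line 38. A loss of both copies of the chromosome around RUNX1 that reached its neighbours is argued against. Of 13 other expressed genes within 1 Mb, 0 were lower in line 38 than in line C4 on all 4 days. SETD4, whose span covers CBR1, stood at 14.5 ppm in line 38 and 11.4 in WT. A loss of 1 copy would lower a gene by about 1 log2 unit at most, the threshold itself, so the count cannot exclude it. Reads of CBR1 assigned to its paralog CBR3 are argued against too, because CBR3 stood at no more than 0.706 in any library of line 38. With CBR1, MAGEH1 and KLF8 on chromosome X were the 3 genes below 1 ppm in every library of line 38 and at 3 or more in all others, against 0 such genes for line C4 and 0 for WT. MAGEH1 was also lower in line C4, at 12.17 ppm on average against 52.45 in WT. CTHRC1 stood at no more than 0.302 in line 38, but its lowest library of line C4 held 0.907. For CBR1 a candidate source is a change private to the clone, at the gene itself or in its silencing, which sequencing of the locus would test. SETD4 was named after its values were seen.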

How the results depend on the processing

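Leaving out the third library of each line at day 12, and list tests of each line, with a library left out or with the block, were chosen after the data were seen, and all other alternatives before the data were examined. With 1 library left out, all 144 counts of called genes stayed within 1.5 times and all 36 values of RUNX1 were unchanged in direction and call. Under the other settings 120 of 157 counts and all 37 RUNX1 values did so. Of named genes that led a comparison, 923 of 927 values held with 1 library left out and 923 of 927 under other settings, and 4 of each lost their call with the same direction. Of the counts of called list members 863 of 936 held with 1 library left out and 842 of 962 under other settings. Read depth was not analysed here, so its effect on low genes is open, and genes at the top of their GC class cannot rise. Quantile normalization moved no fold change by more than 0.0625, so it tests nothing.

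A pseudocount of 0.1 called 867 genes for the knockout at day 6 and 1863 at day 9, because it widens changes of low genes. A pseudocount of 5 narrows them and called 175, 470, 1966 and 1852 for the knockout on the 4 days, 47, 279, 1648 and 1505 in both lines, 396, 218, 120 and 178 between the lines, 320, 1737 and 2136 in WT over time, 1580 in the knockout over time and 1872 for genotype by time. With no minimum fold change, which only relaxes the call, the counts in that order were 2092, 6315, 10257 and 10020, then 345, 3226, 7880 and 7425, then 4430, 1882, 940 and 1290, then 2733, 8775 and 10226, then 11054 and 7543. A fit to day 12 alone, with fewer libraries, gave 204 genes between the lines.

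With an estimated correlation 24 list tests of the knockout lost their call, and the cause was not tested. Their adjusted p at day 6 was 0.0683 for arterial, 0.397 for haematopoietic transcription factors, 0.52 for erythroid, 0.397 for megakaryocyte, 0.428 for mesenchymal stem cell surface, 0.128 for fibroblast matrix and 0.12 for endoderm genes. At day 9 it was 0.132 for endothelial, 0.341 for arterial, 0.477 for erythroid, 0.0893 for mast cell, 0.285 for endoderm and 0.398 for cell cycle genes. At day 12 it was 0.606 for endothelial, 0.648 for erythroid, 0.297 for endoderm, 0.128 for cell cycle, 0.132 for interferon and 0.544 for hypoxia genes, and at day 16 0.627 for erythroid, 0.245 for endoderm, 0.236 for cell cycle, 0.215 for interferon and 0.475 for immediate-early genes.

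The balance of called members changed side for 3 lists. With no minimum fold change 7 lymphoid genes were called at day 16, 13 TGF-beta and BMP targets at day 12, and 4 and 5 genes of the RUNX family at days 9 and 16, because small changes were added. The TGF-beta count at day 12 ranged from 2 to 5 with 1 library left out, and was 5 without WT library 1, without line 38 library 3, and without the third library of each line. The cause was not tested.

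Pairing by replicate number was not settled, since the labels name no source of it and 22 of 36 pairs of the same number correlated above 0.1. All 3 pairs did so for line 38 and line C4 at day 6 (0.158, 0.166 and 0.151) and for WT and line 38 at day 12 (0.375, 0.160 and 0.507). The third libraries of day 12 also correlated at 0.457 between WT and line C4 and at 0.507 between lines 38 and C4. Same numbers correlated above other numbers on average in 11 of 12 comparisons of 2 lines, and in 2 every library correlated best with its own, so shared handling of some libraries stays open. With the replicate number as a block the counts were 542, 1099, 3415 and 3231 for the knockout, 161, 632, 2766 and 2548 in both lines, 1099, 643, 358 and 458 between the lines, 826, 3073 and 3779 in WT, 2855 in the knockout over time and 3261 for genotype by time, none moved by over 1.5 times. Of 80 list tests called at the preset correlation, on the knockout and between the lines, 79 stayed called under the block. Of the lists, mesenchymal stem cell surface genes at day 6 lost it (adjusted p = 0.0489 without and 0.0658 with the block) and endothelial genes at day 16 gained it (0.0519 and 0.0389). With an estimated correlation 17 of 23 stayed called. The other 6 were endothelial genes at day 6 (0.04 without and 0.0642 with the block), myeloid and interferon genes at day 9 (0.0299 and 0.04 without, both 0.0904 with), and between the lines smooth muscle at days 12 and 16 (both 0.0301 and 0.119) and epithelial-mesenchymal regulators at day 12 (0.016 and 0.117). Without the third library of each line at day 12 the knockout had 3498 genes there, both lines 2892, the lines between them 239 and WT over time 3074.

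Of 100 splits of the libraries for the knockout, only the real one gave as many genes on each day, a share under 0.05. The real counts were 533, 1092, 3412 and 3228 and the highest other 451, 443, 1667 and 3222, the last with WT kept together and the knockout lines mixed. In both lines 4, 2, 2 and 1 of 100 gave as many, also shares under 0.05, with 141, 619, 2763 and 2537 real and 755, 814, 2962 and 348 highest other. The 755 came from line C4 taken as reference, several times the real count, which points to the structure of the samples, and 814 and 2962 from WT kept together. At days 6, 9 and 12 this count therefore does not single out the real grouping. The splits show that the lines differ, not whether RUNX1 or the line is the source. For the knockout over time 1 of 100 gave as many, with 2854 real and 1540 highest other. For WT over time the 10 splits are too few, with 802, 3061 and 3775 real and 1, 45 and 0 highest other.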

Other observations

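The tests of explanations for the endoderm genes were chosen after their values were seen. Single members of lists outside blood and mesenchyme also differed between knockout and WT. Of 11 pluripotency genes 2 were lower at day 6, POU5F1 at -1.19 (SE 0.28, adjusted p = 0.00356) and NANOG, its partner in stem cells, at -1.39 (SE 0.21, adjusted p = 2.83e-05). Just 1 of them passed without WT library 2. At day 9 POU5F1 stood at 9.48 ± 1.75 ppm in WT, 1.14 ± 0.434 in line 38 and 2.34 ± 1.12 in line C4 (SD, n = 3). ZFP42, another stem cell factor, went the other way, at 1.72 (SE 0.11, adjusted p = 1.15e-13) at day 12 and 1.81 (SE 0.11, adjusted p = 3.56e-14) at day 16. As a list pluripotency genes did not pass on any day (camera adjusted p = 0.798, 0.826, 0.520 and 0.384). Of 7 early mesoderm genes HAND1, a factor of lateral mesoderm and heart, was higher at 1.68 (SE 0.09, adjusted p = 1.49e-15) at day 12 and 1.52 (SE 0.09, adjusted p = 1.37e-14) at day 16 (camera adjusted p of the list = 0.496 and 0.354). Of 13 cardiac genes 2, 4 and 3 were higher at days 9, 12 and 16 and none lower (camera adjusted p = 0.131, 0.158 and 0.0902), and 5 passed at day 16 without WT library 1. The troponin gene TNNT2 stood at 1.54 (SE 0.23, adjusted p = 1.26e-06) at day 12 and the heart factor gene TBX20 at 1.63 (SE 0.16, adjusted p = 1.04e-09) at day 16. The HOXA genes that were lower at days 6 and 9 passed on neither later day, when their medians were -0.38 and -0.92 (camera adjusted p = 0.335 and 0.137). Up to 2 of them passed there with 1 library left out. The knockout effect on them differed between day 16 and day 6 for 3 of 5, all higher, with a median of 1.07 (camera adjusted p = 0.0975). From day 6 the genes fell in WT, with 5 of 5 lower at day 12 and 4 at day 16. The WT medians were -1.52 and -1.44 (camera adjusted p = 0.00706 and 0.0338, and adjusted p = 0.0764 and 0.146 with an estimated correlation). In the knockout 1 was lower at day 16 than at day 6, with a median of -0.19.

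Among the relatives of RUNX1, RUNX3, which blood cells use, was lower at -4.08 (SE 0.15, adjusted p = 1.35e-19) at day 12. RUNX2, the bone factor, and RUNX1T1, a corepressor gene, were higher at 1.68 (SE 0.20, adjusted p = 1.62e-08) and 1.34 (SE 0.13, adjusted p = 6.63e-10) (camera adjusted p of the list = 0.794). CBFB, the partner of RUNX proteins, stood at 0.16, -0.07, -0.19 and -0.68 on the 4 days and passed on none. Of 17 TGF-beta and BMP targets 1 was higher and 2 lower at day 12, and 5 passed without WT library 1 or line 38 library 3. TGFB2 stood at 1.10 (SE 0.26, adjusted p = 7.01e-04) and TGFB1, the ligand that platelets and white cells make, at -1.60 (SE 0.13, adjusted p = 1.79e-11). At day 16 CTGF, a matrix-associated growth factor gene, and TGFB1 were lower (camera adjusted p of the list = 0.233 at day 12 and 0.701 at day 16). Of 13 hypoxia and glycolysis genes 4 were lower and 1 higher at day 12 (camera adjusted p = 0.0415, and adjusted p = 0.544 with an estimated correlation). The lower ones were the glycolysis genes PGK1, LDHA and ENO1 and the oxygen sensor gene EGLN3, with ENO1 at -1.53 (SE 0.20, adjusted p = 1.27e-07). The higher one was the glucose transporter gene SLC2A1, at 1.04 (SE 0.28, adjusted p = 0.00250) and at 2.14 (SE 0.28, adjusted p = 1.96e-07) on day 16. Of 5 neuroectoderm genes at most 1 passed on any day (camera adjusted p = 0.163 at day 6 and 0.496 at day 16).

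More endoderm and epithelium genes were called higher than lower in the knockout on each day. Fewer blood cells would raise all other cell types alike. The list's mean log2 fold change exceeded that of 75 members of other lists by 0.99, 0.96, 1.02 and 1.27 on the 4 days, with an SE between libraries of 0.196. In that measure 6, 4, 6 and 6 of the 6 knockout libraries lay above all 3 of WT. The 75 came from the mesenchymal surface, epithelial-mesenchymal, smooth muscle, cardiac, bone, neuroectoderm and early mesoderm lists, not from the fibroblast, endothelial or pluripotency lists. They include genes that macrophages also make, such as SPP1, at -9.49 at day 12. The endoderm list, the highest on average, was also singled out after its values were seen, so this excess cannot decide the question. At day 16 the list's mean lay 1.16 above the median of all genes (SE 0.190). That excess cannot decide whether a common distribution lifted genes which did not change, because the list was chosen for its high values. The median of all genes also includes blood genes. The ceiling of abundant genes is argued against, because 7 of the 8 called members never ranked in the top 20 of their GC class. These values are consistent with more endoderm-like cells or more of their RNA in knockout cultures, as a hypothesis found and tested on the same data, and whether RUNX1 or the clone sets it stays open since line C4 exceeded line 38 at days 6 and 9. Counting cells with an endoderm marker in both lines and in a rescued line would test it.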
